A study of Rhipicephalus microplus with 2 samples.

How the data were processed

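Transcript tags were measured by LongSAGE in adult ovary tissue of the southern cattle tick, Rhipicephalus (Boophilus) microplus. LongSAGE (long serial analysis of gene expression) takes a short tag beside the CATG site of each cDNA, joins tags in pairs called ditags, links ditags into concatemers, and sequences cloned concatemers. A control library at time zero and a library at 6 h after Babesia infection were compared, with 1 library per group. Total RNA was extracted with a commercial kit, per the labels' protocols. Base calling, trimming and the tag extraction program are not given in the sources used here.

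The deposited files hold the concatemer sequences themselves, 368 for the control library and 703 for the infected library, and no table of tag counts. Per the labels, these sequences are the raw data of the libraries, and the design text states totals of tags and duplicate ditags that the authors extracted. Tag counts were therefore extracted here. Every stretch of 32 to 34 bases between neighbouring CATG sites was taken as a ditag. The 17 bases at each end, read inward from CATG, were taken as its tags. Each distinct ditag, in either orientation, was counted once per library, the usual guard against PCR copies. This gave 6764 tags for the control library and 8750 for the infected library, and 846 and 1612 duplicate ditags, all equal to the totals stated in the labels. Distinct tags numbered 5315 in the infected library, as stated, and 3933 in the control library, where 3937 were stated.

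Tags were compared between the libraries with a 2-sided Fisher's exact test of the tag's count against the rest of its library. The test covered tags with at least 5 counts over both libraries, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. Folds are ratios of tags per 10000 with exact conditional 95% intervals. Against a count of 0, a fold is a bound computed with a floor of 3 counts, worth 4.44 tags per 10000 in the control library and 3.43 in the infected library. Shares carry exact Clopper-Pearson intervals. Intervals of GC content come from 2000 bootstrap draws of clones. Intervals and floors cover counting error only, since ditags amplified by PCR are not independent molecules. With 1 library per group there was no replicate check: each test compares these 2 libraries, not the conditions. The control was taken at 0 h and the infected library at 6 h, so time and infection go together.

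The number of distinct tags was compared after thinning the infected library to the control total in 1000 seeded draws. The number of shared tags was set beside that of random parts of the pooled tags, again in 1000 draws. Sequence names give clones read from both ends and, in the infected library, 2 series of clones whose meaning the labels do not state. These are called series A and series B and served as a technical split. In ditags of 34 bases, a tag kept the same base at position 18 in 98.1% of cases in the control library and 95.6% in the infected library, and at position 19 in 43.0% and 42.5%. Joined tags thus overlap by 2 bases, and 200 draws of random pairing were also made only among tags with matching 2-base ends.

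Tags named in the text followed a rule with 4 parts: up to 12 tags per direction assigned to a named gene, the 3 unassigned tags per direction with the smallest Fisher p, the 8 most frequent tags of each library (of tags with equal counts, the one with the larger total over both libraries), and members of 20 fixed gene lists. No transcript sequences of the tick were used here, so no tag was assigned to a gene. Parts that need genes were therefore empty, and the gene list shares, the share of tags assigned to transcripts and gene sums were not analysed here. Tags are reported by sequence. Other tags named below were chosen after their values were seen.

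The comparisons, the test, the threshold, the naming rule and the alternatives on the count minimum, library totals, merging and artefact tags were set before the data were examined. Other alternatives were chosen after the data were seen. The design had assumed tables of tag counts; the same test was run on the counts extracted here. edgeR was not used here. An exact conditional negative binomial test with an assumed coefficient of variation of 0.2 or 0.4 and a trimmed mean of M-values scaling (trims of 30% and 5%) were computed. Further alternatives were another count minimum, other library totals, merging of tags 1 mismatch from a tag with at least 10 times their count, removal of linker and A-run tags, 16-base tags, other ditag rules, single clone series, and tests among tags of equal GC, with tags of 5 or fewer and of 15 or more G and C pooled.

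The extraction and the test were tested on simulated data. All 716 simulated ditags were recovered. In 20 simulated comparisons of the libraries over 390 tags, 200 of them changed, the test called 4.93% of tags changed 2-fold, 25.6% changed 4-fold and 55.8% changed 8-fold. Of the calls, 0.434% were of unchanged tags, and no tag was called when none was changed. The simulated counts held counting error only, without variation between libraries, PCR copies or GC-dependent loss of ditags. The share of false calls in the real libraries is therefore not known from them. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9 were used.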

Results

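Ovary of the cattle tick Rhipicephalus (Boophilus) microplus was profiled by LongSAGE in a control library at time zero and in a Babesia-infected library at 6 h. Babesia is a protozoan blood parasite of cattle that female ticks pass to their offspring through the egg, so the ovary lies on its route of transmission. The control library held 368 concatemer sequences from 248 clones and gave 6764 tags of 3933 kinds. The infected library held 703 sequences from 424 clones and gave 8750 tags of 5315 kinds. Most kinds of tag were seen once, 80.1% in the control library and 81.8% in the infected library. Only 64 and 67 tags, in that order, reached 10 counts.

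The main comparison asked which transcripts differ between infected ovary at 6 h and control ovary at time zero. Tag ATCTGAGTTTAGACCGA was the most frequent tag of the infected library, at 387 per 10000 (95% interval 348 to 430, 339 counts). It stood at 31.0 per 10000 in the control library (19.2 to 47.4, 21 counts), a 12.5-fold difference (8.03 to 20.4; Fisher's exact test, adjusted p = 4.64e-57). Tag TGATTGTGTGCTATGTG was next, with 142 counts against 1, 162 per 10000 against 1.48, a ratio of 110 (19.4 to 4366; Fisher's exact test, adjusted p = 4.05e-32). Tag GGGGCAAACACTATGGA was counted 85 times in the infected library, 97.1 per 10000, and was absent from the control library. It was thus at least 21.9-fold higher in the infected library against the floor of 3 counts, with an exact lower 95% limit of 17.4-fold (Fisher's exact test, adjusted p = 1.30e-19). Set against tags of equal GC alone, the log2 ratio of ATCTGAGTTTAGACCGA was 1.06 in place of 3.64, that of TGATTGTGTGCTATGTG 4.20 in place of 6.78, and the bound for GGGGCAAACACTATGGA 3.83 in place of 4.45. All 3 tags still passed (highest adjusted p = 0.00161 by Fisher's exact test).

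Other tags were higher in the control library. Tag TGGTGCCCGAAACGAAG stood at 81.3 per 10000 in the control library and 6.86 in the infected library, 11.9-fold higher in the control (5.11 to 33.7; Fisher's exact test, adjusted p = 2.60e-12). Tag TCTGGACGCGGCAAGGG had 38 counts against 2, a ratio of 24.6 (6.35 to 210; Fisher's exact test, adjusted p = 2.72e-10). Tag GACGGCGAGTGGGAACC had 45 counts against 6, a ratio of 9.70 (4.13 to 27.8; Fisher's exact test, adjusted p = 2.14e-09). Among tags of equal GC, the log2 ratios of infected over control were −3.18 in place of −3.57 for TGGTGCCCGAAACGAAG, −3.43 in place of −4.62 for TCTGGACGCGGCAAGGG and −2.08 in place of −3.28 for GACGGCGAGTGGGAACC.

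Of 390 tags with at least 5 counts, 93 passed the adjusted threshold in Fisher's exact test, 41 higher in the infected library and 52 higher in the control library. Of the 41, 27 were absent from the control library, and of the 52, 16 were absent from the infected library. Together the 41 tags held 15.6% of the infected library and 0.695% of the control library. The 52 tags held 15.7% of the control library and 3.03% of the infected library. At an unadjusted p under 0.05, 145 tags differed. Which library held more of the higher tags depended on the setting. A trimmed mean of M-values raised all log2 ratios by 0.54 and gave 49 higher in the infected library and 25 higher in the control, while stated totals with duplicates gave 36 and 75. With an assumed coefficient of variation of 0.4 between libraries, 21 of the 93 remained past the threshold, 15 of them higher in the infected library.

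**Figure D1:**
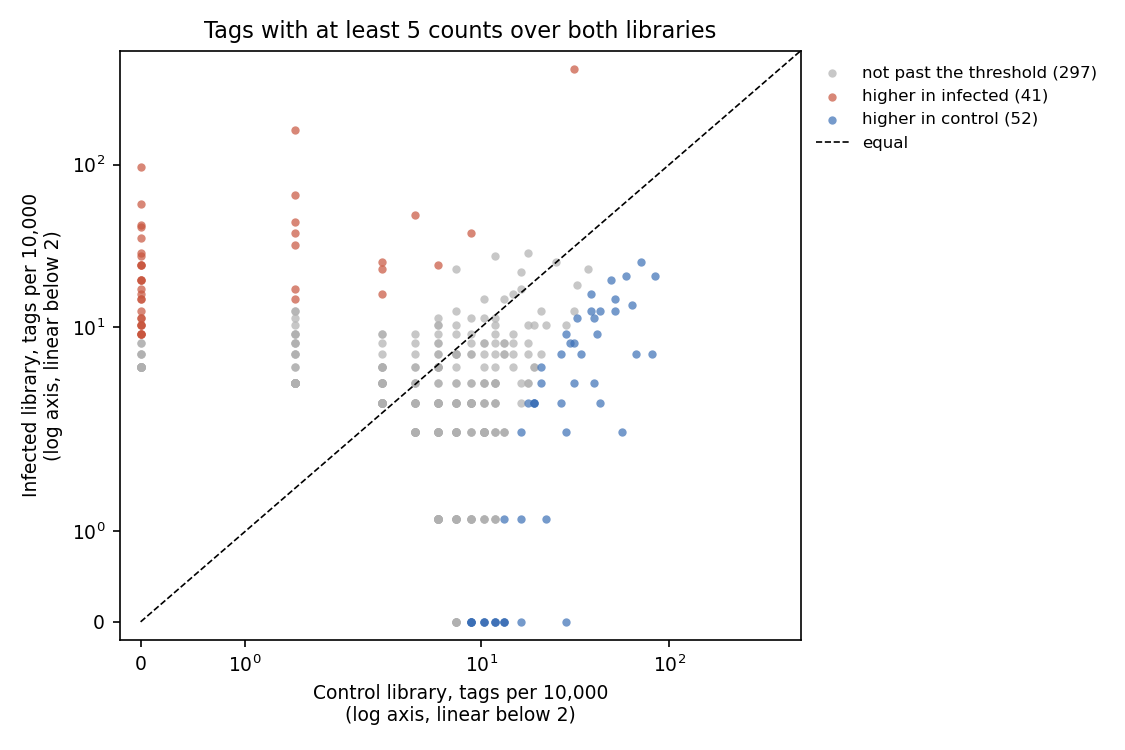
Level of each of the 390 tested tags in the control library (horizontal) and the infected library (vertical), in tags per 10000 on log axes that are linear below 2. Tags past the threshold are coloured, 41 higher in the infected library in red and 52 higher in the control library in blue, and the dashed line marks equal levels.

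The 8 most frequent tags of the infected library all passed the threshold and were all higher there than in the control library. Picking tags by their infected counts favours this direction. Besides the 3 named above, AAGATCACACTGGCATT had 57 counts against 1, a ratio of 44.1 (7.60 to 1771). TTTTCCCCAACCCAGGA had 50 counts and GGTCAAGGGGTAATAAA 37, both absent from the control library, which made them at least 12.9-fold and at least 9.53-fold higher against the floor, with exact lower limits of 10.1-fold and 7.37-fold. TTTTTCCCAACCCAGGA had 39 counts against 1, a ratio of 30.1 (5.10 to 1221), and CAGGCTGTCCCAGCAAT 43 against 3, a ratio of 11.1 (3.55 to 55.8). Tested only against tags of equal GC, AAGATCACACTGGCATT (Fisher's exact test, adjusted p = 0.0926) and GGTCAAGGGGTAATAAA (adjusted p = 0.134) no longer passed. Their log2 ratios were then 2.88 in place of 5.46 and, as a bound, 0.67 in place of 3.25. Both tags have 7 G and C, a class with only 182 tags in the control library and 1411 in the infected library. The bound rests on the floor of 3 counts among those 182. With so few control tags the test is weak, so failing it does not show that GC accounts for these tags. The log2 ratio of TTTTTCCCAACCCAGGA was 3.63 in place of 4.91, the bound for TTTTCCCCAACCCAGGA 3.07 in place of 3.69, and the log2 ratio of CAGGCTGTCCCAGCAAT 3.85 in place of 3.47. CAGGCTGTCCCAGCAAT did not pass with an assumed coefficient of variation of 0.4 (exact test, adjusted p = 0.0665). Each adjusted p given here was the highest of the tag over 17 alternatives. The lowest by Fisher's exact test were 1.73e-38, 7.53e-15 and 2.22e-18, in the same order. These lowest values came from counting all ditags with duplicates, where PCR copies and both reads of a clone count separately. They thus overstate the evidence.

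The 8 tags named as most frequent in the control library were all higher there, a direction that picking by control counts favours. In the last place, CTCACCGACCCGTCGGC and GCCCGCAGCGGCTGAAC both had 35 counts; the first was named for its larger total, with 13 counts against 11 in the infected library, and the other was also higher in the control, 4.12-fold (2.04 to 8.98). ACGTGACTGTCGCCACC, its most frequent tag, stood at 84.3 per 10000 against 20.6 in the infected library, 4.10-fold higher (2.38 to 7.40; Fisher's exact test, adjusted p = 4.54e-07). TACGAAGCGCTGGCAGA was 4.64-fold higher in the control (2.40 to 9.66), CTCACCGACCCGTCGGC 3.48-fold (1.80 to 7.17), ACGCGACTGTCGCCACC 2.87-fold (1.61 to 5.33) and TGGCTGGCTGCCCACTG 2.82-fold (1.67 to 4.91). Their adjusted p values by Fisher's exact test ran from 6.89e-06 for TACGAAGCGCTGGCAGA to 0.00151 for ACGCGACTGTCGCCACC. Among tags of equal GC, the log2 ratio of ACGTGACTGTCGCCACC was −1.13 in place of −2.03 and that of TACGAAGCGCTGGCAGA −1.83 in place of −2.21. There, TGGCTGGCTGCCCACTG, ACGCGACTGTCGCCACC and CTCACCGACCCGTCGGC were below the threshold (Fisher's exact test, adjusted p = 0.825, 0.860 and 0.920), with log2 ratios of −0.30, −0.33 and −0.29 in place of −1.50, −1.52 and −1.80. With an assumed coefficient of variation of 0.4 these 3, ACGTGACTGTCGCCACC and TACGAAGCGCTGGCAGA were all below it (exact test, adjusted p = 0.151 to 0.317). Over 17 alternatives the lowest adjusted p by Fisher's exact test ran from 1.00e-14 for ACGTGACTGTCGCCACC to 1.16e-05 for CTCACCGACCCGTCGGC among these 5 tags. The limits of this range came from counting all ditags with duplicates, which overstates the evidence in the same way.

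**Figure D2:**
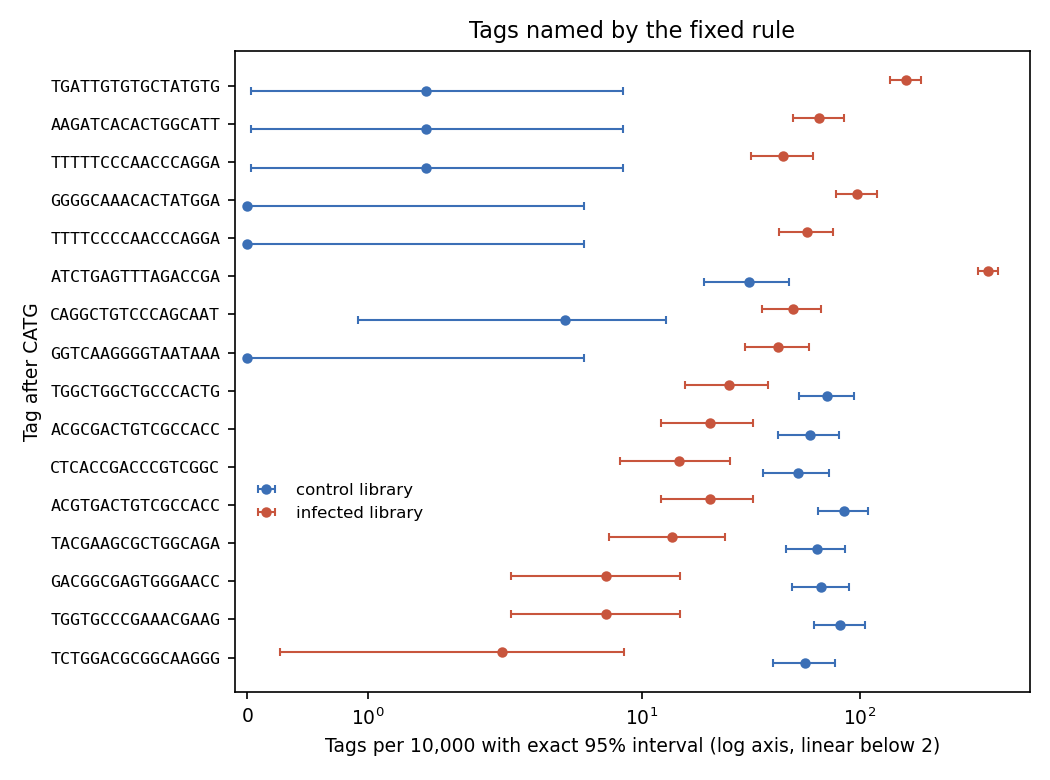
Level of the 16 tags named by the fixed rule in the control library (blue) and the infected library (red), in tags per 10000 on a log axis that is linear below 2. Bars are exact 95% intervals of the counts. Higher in the infected library were 8 tags and higher in the control library 8, directions that the naming rule favours.

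Counts of the most frequent tags depended on how repeated ditags were treated. Counted once per clone in place of once per library, ATCTGAGTTTAGACCGA had 605 counts in the infected library and 25 in the control library, and GGGGCAAACACTATGGA had 181 in the infected library. Tags were carried by many clones: ATCTGAGTTTAGACCGA by 298 of 395 infected clones with a ditag and by 24 of 242 control clones, and TGATTGTGTGCTATGTG by 134 and 1.

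Clone series A and B of the infected library were compared as a technical split, chosen after the data were seen. Tag ATCTGAGTTTAGACCGA had 172 counts in series A and 195 in series B, GGGGCAAACACTATGGA 42 and 49, and TGATTGTGTGCTATGTG 68 and 82. Between the series, 0 of 178 tested tags passed Fisher's exact test after adjustment (7 at an unadjusted p under 0.05, lowest adjusted p = 0.0600). Against the control library, 58 tags passed with series A alone and 55 with series B alone. Of these, 39 passed with both series. Both comparisons share the control library and are parts of the main comparison, so the series give no replicate of infection.

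The composition of the tags differed between the libraries, a comparison added after the data were seen. Mean GC content was 63.4% in the control library and 53.6% in the infected library, a difference of 9.83 percentage points (9.45 to 10.2). Tags with 7 or fewer G and C among 17 bases made up 3.44% of the control library and 25.2% of the infected library. The tags higher in the infected library had a median GC content of 47.1%, and those higher in the control library 70.6%. Among tags below the threshold, the log2 ratio fell with GC content across 297 tags, with Spearman's rho of −0.47 (−0.56 to −0.37). Tags are not independent replicates. Tested against tags of equal GC, 39 tags passed Fisher's exact test, 25 higher in the infected library and 14 higher in the control library, and 33 of them were among the 93.

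**Figure D3:**
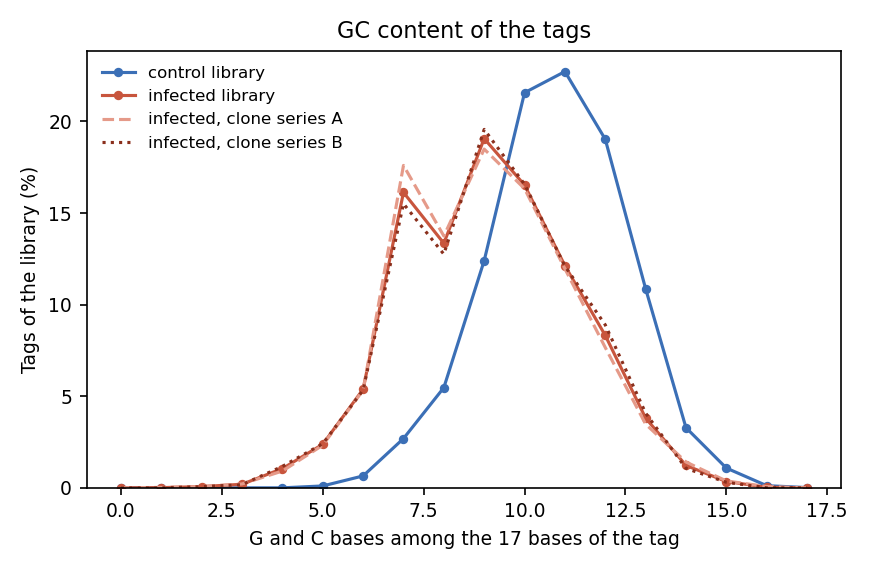
Percentage of the tags of each library (vertical) by the number of G and C among the 17 bases of the tag (horizontal), for the control library, the infected library and series A and B of the infected library. The control library has its peak at 11 G and C bases (22.7%) and the infected library at 9 (19.1%), with both series close to the infected library.

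The word AATAAA, the usual signal for polyadenylation near the end of a transcript, occurred in 2.80% of tags of the infected library (2.46 to 3.17) and 0.429% of the control library (0.287 to 0.615). The ratio was 6.53 (4.43 to 9.96; Fisher's exact test, p = 2.52e-33), and 4.32 without the tags past the threshold. Among the tags past the threshold, 5 of the 41 higher in the infected library carried AATAAA, among them GGTCAAGGGGTAATAAA, and 0 of the 52 higher in the control library. Other 6-base words made of 5 A and 1 T were also more frequent among distinct tags of the infected library. They ran from 4.99-fold for ATAAAA (54 distinct tags against 8) to 27.4-fold for AAAAAT (37 against 1), beside 4.62-fold for AATAAA (100 against 16). The highest fold rests on 1 control tag and is uncertain. Among distinct tags of equal GC, the odds ratio for AATAAA was 1.12 (0.638 to 1.95), and over all tag counts of equal GC it was 1.29 (0.855 to 1.95).

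The number of kinds of tag was compared at equal depth. At 6764 tags, the infected library held 4299 ± 19.0 distinct tags (SD over 1000 draws) and the control library 3933, a difference of 366. The SD covers the thinning alone. With tags 1 mismatch from a far more frequent tag merged, the difference was 285.

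The overlap of the libraries was measured by tags found in both. They shared 798 of 8450 distinct tags, which held 44.8% of the control library and 34.2% of the infected library. Random parts of the pooled tags of the same sizes shared 1157 on average (1097 to 1207 in 1000 draws). Series A and B of the infected library shared 556, where random parts shared 643 (588 to 684). Of tags with at least 2 counts in each library, 276 were shared.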

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

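In this part, the GC difference between the clone series, the count of duplicates within a clone, the values with 1 read per clone and the sum over tags not past the threshold with both series were tests chosen after the result was seen, and pairing through matching ends was added after free pairing had been seen. Outside the tag counts, 7 values were examined over all reads, and 4 were higher in the infected library by Fisher's exact test (highest adjusted p = 0.0342). Sequences with no ditag made up 5.55% of the infected library (39 of 703) and 2.45% of the control library (9 of 368; Fisher's exact test, p = 0.0195). Spacers of 27 to 31 bases, too short for a ditag, made up 5.48% against 4.27% of spacers (Fisher's exact test, p = 0.00169). Spacers of 77 or more bases made up 9.08% against 7.73% (Fisher's exact test, p = 0.00694). Spacers of 0 to 26 bases made up 3.35% against 3.67%, those of 35 to 63 bases 3.75% against 3.43% and those of 64 to 76 bases 1.99% against 1.76% (Fisher's exact test, lowest p = 0.334). In these shares, clones read from both ends counted with both reads, which are not independent. With 1 read per clone, the difference in spacers of 27 to 31 bases turned with the read that was kept. It was 7.55% in the infected library against 2.96% with one read and 3.44% against 5.87% with the other (Fisher's exact test, p = 4.47e-21 and 2.62e-07). Spacers of 0 to 26 bases (4.49% against 3.31% or 2.75% against 4.79%) and of 35 to 63 bases (4.29% against 2.41% or 3.23% against 4.52%) turned likewise, so no direction is given for these 3 lengths. Sequences with no ditag kept their direction, 7.31% against 2.42% or 6.84% against 3.23% (Fisher's exact test, p = 0.00781 and 0.0538), as did spacers of 77 or more bases, 9.39% against 7.83% or 9.18% against 7.995% (p = 0.0127 and 0.0654 by Fisher's exact test). Ditags that repeat a ditag of another clone made up 10.3% against 5.16% of ditags counted once per clone (Fisher's exact test, p = 4.61e-18). Repeats of the same ditag are not independent, and 5 ditags held 158 of the 501 repeats of the infected library. This p thus overstates the evidence. Depth differed too, with 4876 ditags against 3566. Series A and B alone, with 2368 and 2508 ditags, had 10.1% and 8.09%.

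The larger share of duplicates in the infected library was 6.92 percentage points over all ditags. With each ditag counted once per clone the difference was 5.11 points, 74.0% of that value. Reading both ends of a clone was thus not the source of the whole excess. The denominators differ, all ditags against ditags counted once per clone, so 74.0% does not divide the excess by source. Free random pairing of the tags gave 62.9 duplicates between clones (40 to 89) with tags counted once per library and 153 (112 to 208) with tags counted once per clone, where 501 were observed. Pairing only tags with matching 2-base ends gave 191 (148 to 230) and 307 (281 to 341), in the same order. Chance pairing may thus account for part of the duplicates, and PCR copies and chance pairing cannot be told apart because the true tag frequencies are not known.

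The lower GC content of the infected library was not carried by the abundant tags, since 8.34 points (7.91 to 8.76) were left without the tags past the threshold. The clone series differed by −0.470 points (−1.03 to 0.102), which argues against them. GC-dependent gain or loss of ditags is a candidate explanation of the shift over all tags, with a rho of −0.47. A different set of transcripts would give the same trend. A gain or loss that follows the GC of the single tag was not the source of all calls, since 39 tags passed among tags of equal GC. That test leaves out the GC of the joined tag, so a loss that depends on both tags stays open for the calls. Joined tags had GC contents correlated at −0.380 in the control library and −0.171 in the infected library, a difference of −0.209 (−0.252 to −0.166), consistent with loss of ditags of low GC in both tags from the control library. A position nearer the polyadenylation signal stays open, as do infection and time: the AATAAA odds ratio at equal GC was 1.12 (0.638 to 1.95), and the bound set beforehand, an interval that includes 1, was too loose, since 16 control tags with AATAAA leave an interval that also reaches 1.95.

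Of the tags past the threshold, 34 were higher in the infected library with 0 or 1 counts in the control library. A few clones were not the source, since these tags lay in a median of 17 clones (7 to 152). With series A alone 26 passed (76.5%) and with series B alone 27 (79.4%), both under the 80% set beforehand; 20 passed with both. For the other 14 a single series stays open: 8 had at least 3 counts in both series and 1 was absent from one, and the ratio of their summed counts in the series where each had fewer to those in the control library, 30.1, decides nothing because the tags were picked for 0 or 1 control counts. Loss of low-GC ditags from the control library, another organism such as the parasite or the host, and infection or time may each account for some of them. Errors at 1 base in a far more frequent tag stay open for others. Among the 34, tags with 14 and 8 infected counts lie 1 mismatch from the most frequent tag of the infected library. With tags 1 mismatch from a far more frequent tag merged, 39 of all 41 tags higher in the infected library still passed. Of the 41, 21 also passed among tags of equal GC.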

How the results depend on the processing

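The trimmed mean, the coefficients of variation, the clone series, GC and ditag alternatives and 16-base tags were chosen after seeing the data. No named tag changed direction. With another count minimum or an assumed coefficient of variation the log2 ratio stays the same, so direction could not change there. All alternatives reuse the reads from which these tags were picked, so the tally is no independent check. Of 272 comparisons of the 16 named tags with an alternative, 259 kept direction and side of the threshold and 13 fell below it: 6 with a coefficient of variation of 0.4, 5 among tags of equal GC, and ACGCGACTGTCGCCACC with the trimmed mean (adjusted p = 0.0771 by Fisher's exact test) and with a coefficient of variation of 0.2 (adjusted p = 0.0534 by the exact test; 1.84e-06 to 0.860 over its 17 alternatives).

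The 93 calls became 39 with no count minimum (20 higher in infected, 19 in control), since far more tags were then tested, and 21 with a coefficient of variation of 0.4 (15 and 6). They became 58 and 55 with series A or B alone, where fewer counts were tested (26 and 23 higher in control), and 39 among tags of equal GC (25 and 14). Counting all ditags gave 162, of them 115 higher in control; this counts both ends of a clone separately. The 52 higher in control became 25 with the trimmed mean, 31 with a coefficient of variation of 0.2, 80 with each ditag once per clone and 90 with clones carrying the tag; the cause was not tested. Stated totals with duplicates lowered all log2 ratios by 0.13 and gave 111. The other 6 alternatives gave 89 to 107. The balance turned: with more tags higher in control in the main setting, more were higher in infected with the trimmed mean (49), a coefficient of variation of 0.4, equal GC, no count minimum, series A (32) and series B (32).

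The equal-depth difference became 285 with merged tags, and 276 tags were shared at 2 or more counts in each library. The GC difference was 8.32 points with each tag once, 8.34 without called tags, 10.2 with each ditag once per clone and 10.2 with all ditags. edgeR alternatives and those that need genes were not run. No paired analysis was possible because each group has 1 library. Depth limits the calls: the floor of 3 counts for an absent tag is 4.44 per 10000 in the control library and 3.43 in the infected library, and the 2-sided exact interval reaches 5.45 and 4.21.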

Other observations

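In this part, all tests were chosen after the result was seen. Each of the 5 most repeated ditags of the infected library held ATCTGAGTTTAGACCGA or GGGGCAAACACTATGGA, and none held TGATTGTGTGCTATGTG, its second most frequent tag. ATCTGAGTTTAGACCGA joined to GGGGCAAACACTATGGA was found in 53 clones, 23 of series A and 30 of series B. With tags counted once per clone, free pairing gave 11.2 on average, and pairing through matching 2-base ends gave 35.4 (24 to 46 in 200 draws). AAGATCACACTGGCATT joined to ATCTGAGTTTAGACCGA was found in 49 clones, where free pairing gave 7.94 and matching ends 36.9 (25 to 49). ATCTGAGTTTAGACCGA joined to CAGGCTGTCCCAGCAAT was found in 24, where they gave 5.65 and 23.2 (15 to 36). The remaining ditags lay in 19 clones, where matching ends gave 8.25 (3 to 17), and in 18, where they gave 11.5 (5 to 18). With matching ends, 2 of the 5 thus lay above all draws and 3 within their range. Tags counted once per clone include the repeats under test, which raises the expected values. Over all repeats between clones in the infected library, matching ends gave 191 with tags counted once per library and 307 once per clone. A place within the range therefore decides nothing about chance pairing. Pairing with tags counted once per library was not tested for single ditags. The 5 most repeated ditags made up 31.5% of the 501 repeats between clones in the infected library and 7.07% of the 184 in the control library, where the most repeated ditags lay in 4 clones.

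Some frequent tags had a close relative that differs at 1 base. Among 167 tags with at least 10 counts over both libraries, 8 such pairs were found. Positions are counted from 1 at the base after CATG. TTTTCCCCAACCCAGGA and TTTTTCCCAACCCAGGA (C5T) had 50 and 39 counts in the infected library and 0 and 1 in the control library. AAGATCACACTGGCATT and AAGATCACGCTGGCATT (A9G) had 57 and 24 in the infected library and 1 and 0 in the control library. ACGTGACTGTCGCCACC and ACGCGACTGTCGCCACC (T4C) had 57 and 40 in the control library and 18 and 18 in the infected library. The rarer member had 41.4% to 83.3% of the counts of the other in 6 pairs. In the 2 pairs with ATCTGAGTTTAGACCGA, the most frequent tag, it had at most 3.89%. Alleles and copies of a gene were not told apart.

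Tag ATCTGAGTTTAGACCGA may come from the large-subunit ribosomal RNA of the mitochondrion. It differs at 2 of 17 bases (C10T and G17A, from the site to the tag) from the conserved site bound by the 16Sbr primer. Only the 17 bases of the tag were compared, not the CATG before it, which this tag also needs. For 1 fixed site and equal base frequencies, chance gives 0.000628 tags as close. The site was chosen after the tag was seen, so this value does not measure how likely such a match is. Apart from rarer variants of this tag, some of them at 1 mismatch from the site, the nearest tag of either library had 5 mismatches. The match gives no species, so a mitochondrion of the tick, of the host or of the parasite stays open, and no tick sequence was used here to test it.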
